A study of Arabidopsis thaliana with 16 samples.

How the data were processed

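Total RNA came from 3-week-old Arabidopsis plants grown at 22 degrees C under a 14 h photoperiod at about 125 microeinsteins per square metre and second, per the labels' protocols. Fungus kept for 10 to 12 days on squash was applied in settling towers 1.3 m tall, and inoculated plants were sampled 3 days later. For each array 20 micrograms of biotinylated cRNA were hybridized to an ATH1 array.

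The deposited value table holds an intensity per probe set and array on a linear scale. Per the labels' protocols, the authors analysed the array images with Microarray Suite 5.0 at a target intensity of 500 and imported the data into GeneSpring 4.2; the reference values that GeneSpring normalized were not used here. The values bear out the scaling, since the mean after trimming 2% of probe sets at each end lay between 500.04 and 500.06 on every array. The deposited hybridization records, text entries of the unit called other, gave the day, run, fluidics station and module of each of the 16 arrays, and their descriptions matched the labels for all 16. Background correction and probe summarization were done by the authors' software, with settings not given in the sources used here.

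Probe sets were named from a platform table that pairs 13513 probe sets with 1 gene, 503 with several and leaves 8794 unlisted; only those with 1 gene were named, and 13436 of these matched a newer gene table (assembly TAIR10.1) by locus. Because the build behind the array design is not given in the sources used here, no coordinates are printed. The 64 control probe sets were left out, and of the other 22746 the 15420 with a signal of at least 100 on at least 4 arrays were tested, 8472 of them (54.9%) with a named gene. Signals were transformed as log2(signal + 16), so that changes of dim genes are understated. A linear model with 4 group means over all 16 arrays (12 residual degrees of freedom) was fitted with limma 3.58.1 in R 4.3.3, moderated with eBayes, and 5 contrasts were taken: the inoculation response in each genotype, the genotype difference in each treatment, and the difference between the responses. Adjusted p-values are Benjamini-Hochberg values over the 15420 probe sets of a contrast, and a probe set was called at an adjusted p under 0.05. Where a gene has several probe sets, the brightest stood for it in the gene lists.

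Gene lists were tested with camera (limma) at a preset correlation between genes of 0.01, with the estimated correlation as an alternative, and adjusted over the lists and contrasts of their family. Of 21 lists fixed before the data were examined, 3 had at least 3 measured genes: defence-related WRKY factors, protein folding in the endoplasmic reticulum, and photosynthesis. The other 18 were not tested, and 10 of the 21 had no measured gene. Of the 323 genes in the fixed lists 26 had a named probe set, and 21 of these were measured. Most list genes were thus missing for want of a name in the platform table, not of signal. A second family of 18 lists was drawn up from the names in the platform table, before any comparison of groups: defence- and salicylate-associated genes, jasmonate and ethylene genes, endoplasmic reticulum folding and quality control, UDP-glycosyltransferases, glutathione transferases, SWEET transporters, the CYP71B family, plastid-encoded and nuclear photosynthesis genes, expansins and xyloglucan endotransglucosylases, calmodulin-like proteins, ATG8 proteins, cold and dehydration responsive genes, trichome birefringence-like genes, subtilases and vacuolar processing enzymes, AGAMOUS-like and pollen or floral regulators, beta-glucosidases, and heat shock chaperones. The groups, contrasts, tests, fixed lists, most alternatives and the rule for naming genes were chosen before the data were examined.

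Names were taken by that rule from, for each contrast, the 8 called genes with the largest rise and the 8 with the largest fall whose 4 signals per group do not overlap (called only, for the difference between responses), and of each list up to 4 called members with the largest change, or the member with the largest change where none was called. A gene named in 1 contrast may be named in others. A further part of the rule, always to name PMR4, PR1, PR2, PR5, ICS1, PAD4 and EDS1, could not be met because none had a named probe set. ATG8C was named after its value was seen.

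Replicate numbers in the labels run from 1 to 4 in each group. The deposited hybridization records show that arrays with the same number were hybridized in the same run, each of the 4 runs holding 1 array of each group, with replicates 2 and 3 on day 1 and replicates 1 and 4 on day 2. This was taken as the pairing before any fit. The main fits held no term for the run, which entered only as an alternative, the replicate block. Deviations from the group means correlated at a mean of 0.0827 between arrays of the same run (11 of 24 pairs over 0.1, from -0.144 to 0.314), at 0.0246 between runs of the same day and at -0.0501 between days; for replicate 4 the mean was 0.189, with 6 of 6 pairs over 0.1. Because each run and each day holds every group equally, list means and log2 changes with the run or day as a block equal those without, and only the errors change. Within a run each group has 1 array, so no within-run test was made.

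The alternatives were a pseudocount of 1 or 64, no filter or a minimum signal of 200, quantile normalization, division by the median signal, an intensity trend in eBayes, array quality weights, a fit to only the groups compared, the replicate number or the hybridization day as a block, a 2-fold minimum, an adjusted p under 0.01, 1 probe set per named gene, all probe sets of each gene in the lists, the estimated correlation, and leaving out each array in turn. Taking 1 probe set per named gene also left out every probe set not matched to a gene by locus. Each day alone and the 12 arrays without replicate 4 were added after the data had been seen. No scaling moved the median log2 change of all tested probe sets beyond 0.1 on the log2 scale.

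The fit was tested on simulated data with 200 of 15420 probe sets changed, 50 at each size. Of those changed by 1 on the log2 scale, 76% were called in the wild-type response, 72% in the pmr4 response, 80% and 78% in the genotype contrasts of uninoculated and inoculated plants, and 52% in the difference between responses, where 98% were called at a change of 2. For changes of 0.5 the last value was 4%. The Benjamini-Hochberg cutoff is looser where more probe sets change. In the real data the genotype contrasts had 75 and 56 calls and the difference between responses had 2, so the simulated shares can overstate the power there. RNA quality was read from the ratio of 3' to 5' signal of 6 controls (log2), actin, GAPDH and ubiquitin in a newer and an older set of control probe sets, in 24 exact permutation tests (two-sided) between groups, where 4 arrays against 4 cannot give p below 0.0286; the lowest exact p was 0.0857 and the lowest adjusted value 0.800.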

Results

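Transcript levels were measured in 3-week-old Arabidopsis thaliana plants on 16 single-colour oligonucleotide arrays carrying 22810 probe sets. The arrays formed 4 groups of 4 biological replicates: wild-type Columbia-0 plants and pmr4-1 mutants, which lack a callose synthase, each either uninoculated or 3 days after inoculation with the powdery mildew fungus Erysiphe cichoracearum. Callose is a glucan that plants deposit in the cell wall at sites of attempted fungal entry. With callose, defence and salicylic acid among the labels' keywords, the design asked how loss of this enzyme changes transcript levels before and after infection. Median signals ran from 174.5 to 205.85 across the arrays, and 60.7% to 66.1% of probe sets on an array reached a signal of 100. Replicates of a group correlated at r of 0.945 to 0.983 over log2 signals across the probe sets that were tested, and no array was identical to another. The PMR4 transcript itself, and the salicylic acid markers PR1, PR2, PR5, ICS1, PAD4 and EDS1, had no probe set paired with them in the platform table used here, and their levels were not analysed here. The genotype labels were therefore not checked on the mutated gene.

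The first principal component, with 33.1% of the variance, placed the groups in the order uninoculated wild type (-33.4 to -28.8), uninoculated pmr4 (-19.0 to -11.4), inoculated wild type (11.7 to 21.6) and inoculated pmr4 (23.7 to 43.0), with no overlap between groups. On the second component, with 13.5%, the inoculated arrays of replicate 4 lay at -32.5 in wild type and -30.3 in pmr4, against 6.10 to 21.8 for the other 6 inoculated arrays. The uninoculated arrays of replicate 4 were also the lowest of their groups there, at -11.3 in wild type against -1.69 to 3.47 and at -19.2 in pmr4 against -6.59 to 8.15. Replicate 4 arrays of all groups were hybridized in the same run.

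**Figure D1:**
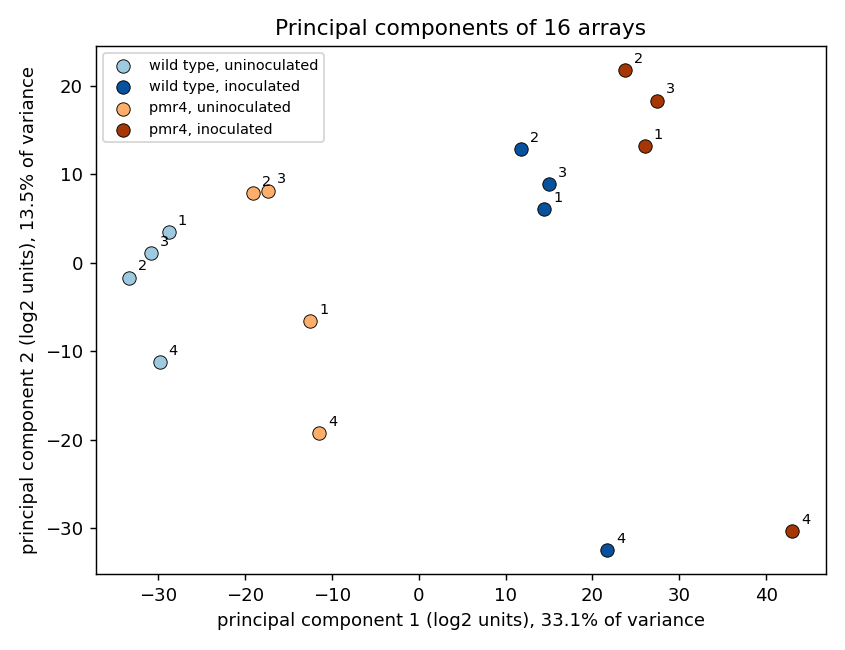
The 16 arrays on the first 2 principal components of log2 signal, with the share of variance of each component on its axis, coloured by group and numbered by replicate. The 4 groups do not overlap on the first component, and the 2 inoculated arrays of replicate 4 sit near -30 on the second.

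The response of wild-type plants to the fungus was the contrast of inoculated with uninoculated Columbia-0, 4 arrays against 4. Changes are given as log2 change ± standard error on the log2(signal + 16) scale, so for a gene with signals under 100 in a group the size depends on the 16 added. CHI (AT2G43570), a chitinase-like protein, rose from a signal of 266 ± 78.4 (SD, n = 4) to 3054 ± 614 (SD, n = 4), a log2 change of 3.46 ± 0.22 (adjusted p = 4.8e-08). AT1G26380 and AT1G26420, oxidoreductases of the berberine bridge enzyme family, rose by 3.497 ± 0.39 and 2.68 ± 0.19, and the lectin-like gene AT5G18470 by 2.70 ± 0.15 (adjusted p = 6.0e-09). AT1G13470, AT3G18250, AT5G52760 and AT2G18690 rose by between 2.58 and 2.93. Among the named genes that fell without overlap of the signals, AT5G62280 changed most at -3.05 ± 0.27 (adjusted p = 1.1e-06), followed by AT5G50335 (-2.24), AT5G45310 (-2.12), the expansin-like genes EXLA2 (AT4G38400, -2.04 ± 0.37) and EXLA1 (AT3G45970, -1.91 ± 0.22), the transcription factor MYBC1 (AT2G40970, -1.90) and AT5G57340 (-1.82). AT2G15830 stood at -1.65 with adjusted p = 0.0267, a call lost without uninoculated replicate 2 (0.0825) or 4 (0.0690) or inoculated replicate 1 (0.0609) or 4 (0.0705).

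Of the 33 measured genes in the list of defence- and salicylate-associated genes, 26 rose in wild type and none fell, with a mean log2 change of 1.52 (camera, adjusted p = 2.9e-34, and 0.000466 with an estimated correlation). On hybridization day 1 the mean was 1.70 and on day 2 it was 1.33. SAG101 (AT5G14930), a lipase-like partner of EDS1 in immune signalling, rose by 1.02 ± 0.18, the glutaredoxin GRX480 (AT1G28480) by 1.08 ± 0.19, the subtilase SBT3.3 (AT1G32960) by 1.26 ± 0.28 and the cytochrome P450 CYP71B23 (AT3G26210) by 2.04 ± 0.15. In the list of defence-related WRKY transcription factors fixed in advance, 3 of 25 genes were measured. Of these WRKY53 (AT4G23810, 2.13 ± 0.36) and WRKY6 (AT1G62300, 1.23 ± 0.25) rose, 2 over all probe sets and 2 adjusted over the list alone. The list mean was 1.14 (adjusted p = 0.0268, and adjusted p = 0.265 with an estimated correlation), 1.28 on day 1 and 1.01 on day 2. Without inoculated wild-type replicate 1 the list lost its call, at a mean of 1.098.

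Genes for protein folding in the endoplasmic reticulum rose as well. In the list fixed in advance, with 4 of 18 genes measured, 3 rose over all probe sets and 4 adjusted over the list alone. Their mean was 0.68 (adjusted p = 0.00088, and adjusted p = 0.112 with an estimated correlation), 0.605 on day 1 and 0.76 on day 2. ATERDJ3B (AT3G62600), a luminal co-chaperone, rose by 1.19 ± 0.18 and the calreticulin CRT1b (AT1G09210) by 0.56 ± 0.12. In the wider list of 18 folding and quality control genes 6 rose and none fell, with a mean of 0.38 (adjusted p = 1.4e-05, and 0.0101 with an estimated correlation; 0.39 on day 1 and 0.37 on day 2). BZIP60 (AT1G42990), a transcription factor of the unfolded protein response, rose by 0.80 ± 0.12, and AT3G60540 by 1.12 ± 0.18.

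Expansins and xyloglucan endotransglucosylases, which loosen and remodel the wall, were lower as a list of 14 measured genes, with 1 higher and 3 lower and a mean of -0.38 (adjusted p = 0.0465, and adjusted p = 0.243 with an estimated correlation). The mean was -0.43 on day 1 and -0.34 on day 2, and with the hybridization day as a block the adjusted p of this list was 0.0519. EXPA8 (AT2G40610, -0.98 ± 0.12), EXLA1 and EXLA2 fell, and EXPA9 (AT5G02260) rose by 0.67 ± 0.16. Of 9 measured cold and dehydration responsive genes, 4 fell and 1 rose, with a mean of -0.33 (adjusted p = 0.00749, and adjusted p = 0.227 with an estimated correlation). Within the days the mean was -0.24 and -0.43. The dehydrin COR47 (AT1G20440) fell by 1.05 ± 0.11 and the chloroplast protein COR15A (AT2G42540) by 1.42 ± 0.26, while COR27 (AT5G42900) rose by 2.11 ± 0.25. Neither photosynthesis list passed the test in wild type. The 43 plastid-encoded genes had a mean of -0.14 (adjusted p = 0.195) with 3 lower and none higher. The 36 nuclear genes had a mean of -0.14 (adjusted p = 0.0615), also with 3 lower and none higher. ATG8 genes did not pass in wild type either, with a mean of -0.10 (adjusted p = 0.582), 1 higher and 2 lower of 9, nor did 4 calmodulin-like genes (0.15, adjusted p = 0.681, none called). The photosynthesis list fixed in advance, with 4 genes measured, had no gene called over all probe sets or adjusted over the list alone in any comparison (mean -0.01 in wild type, adjusted p = 0.973).

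Over all 15420 probe sets tested in wild type, 870 were higher and 710 lower after inoculation at an adjusted p under 0.05 (limma), 319 and 110 of them by at least 2-fold, and 421 and 358 had a named gene. The lower count fell to 457 without uninoculated wild-type replicate 1 and to 449 without replicate 2. With the hybridization day as a block the counts were 935 and 788. The 8 arrays of day 1 alone gave 631 higher and 369 lower, and the 8 of day 2 alone 150 and 65, each from 2 arrays per group.

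The same contrast in pmr4 gave 942 probe sets that were higher and 731 that were lower (limma, adjusted p under 0.05), 338 and 37 of them by at least 2-fold, with 462 and 380 named. The named gene with the largest rise was AT3G28510, an AAA-type ATPase, at 3.70 ± 0.27, from a signal of 29.4 ± 23.8 (SD, n = 4) to 526 ± 73.3 (SD, n = 4). It was followed by AT1G57630, which encodes a TIR domain protein (3.39 ± 0.32), AT3G18250 (3.20 ± 0.13) and AT3G13610, a feruloyl-CoA hydroxylase of coumarin synthesis (3.06 ± 0.33). Next came CHI (3.00 ± 0.22), AT2G44240 (2.93 ± 0.29), AT1G26390 of the berberine bridge enzyme family (2.83 ± 0.26) and AT4G12490 (2.76 ± 0.19). Falls were smaller: AT3G46370 (-1.56 ± 0.32, with mean signals under 100 in both groups), AT5G55620 (-1.24 ± 0.20), AT2G29290 (-1.21 ± 0.18), AT3G24190 (-1.14 ± 0.25), AT2G36145 (-1.10 ± 0.16) and the sucrose transporter SWEET13 (AT5G50800, -1.06 ± 0.16). AT3G52860 (-1.28, adjusted p = 0.0333) and AT5G02440 (-1.06, adjusted p = 0.0165) were lower too. The first call was lost without uninoculated pmr4 replicate 1 (0.0753), 3 (0.0939) or 4 (0.0643) or inoculated replicate 3 (0.0546), and the second without uninoculated replicate 3 (0.0511).

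In pmr4, 26 of the 33 defence- and salicylate-associated genes rose and none fell, with a mean of 1.56 (adjusted p = 6.9e-37, and 0.000466 with an estimated correlation). By day the mean was 1.72 and 1.399. SBT3.3 rose by 2.21 ± 0.28, SAG101 by 1.12 ± 0.18, GRX480 by 1.26 ± 0.19, CYP71B23 by 1.69 ± 0.15 and the receptor-like cytoplasmic kinase BIK1 (AT2G39660) by 0.88 ± 0.18. Among the WRKY factors, WRKY53 rose by 1.76 ± 0.36 and WRKY6 by 1.56 ± 0.25, 2 over all probe sets and 2 adjusted over the list alone. The list had a mean of 1.03 (adjusted p = 0.0486, and adjusted p = 0.298 with an estimated correlation). On day 1 it was 1.495 and on day 2 it was 0.57, the latter with adjusted p = 0.28. The WRKY call in pmr4 was lost on leaving out any of 7 single arrays. The fixed folding list had 3 genes higher over all probe sets and 4 adjusted over the list alone. Its mean was 0.59 (adjusted p = 0.00126, and adjusted p = 0.112 with an estimated correlation), 0.51 on day 1 and 0.67 on day 2. The wider folding list had 8 genes higher and none lower (mean 0.43, adjusted p = 8.9e-07, and 0.00525 with an estimated correlation), and means of 0.38 on day 1 and 0.48 on day 2. BZIP60 rose by 0.98 ± 0.12 and OS9 (AT5G35080), a lectin of glycoprotein quality control, by 0.57 ± 0.13.

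Nuclear genes of photosynthesis and chlorophyll synthesis were lower in inoculated pmr4 as a list of 36, with 4 called lower and none higher. Their mean was -0.18 (adjusted p = 0.00882, and adjusted p = 0.350 with an estimated correlation), -0.33 on day 1 and -0.03 on day 2. The thylakoid calcium sensor CaS (AT5G23060) fell by 0.60 ± 0.11 and NdhL (AT1G70760), a subunit of the chloroplast NDH complex, by 0.64 ± 0.11. Without the 4 replicate 4 arrays the list mean was -0.25 (adjusted p = 1.8e-05). The 43 plastid-encoded genes had a mean of -0.04 and a median of 0.00 (adjusted p = 0.914) with 1 higher, and the cold and dehydration genes a mean of 0.08 and a median of -0.12 (adjusted p = 0.883) with 1 higher and 1 lower. Of 9 measured ATG8 genes, whose products form the autophagosome membrane tag, ATG8D (AT2G05630, 0.86 ± 0.15), APG8A (AT4G21980, 0.86 ± 0.16) and APG8H (AT3G15580, 0.75 ± 0.14) rose and none fell. The ATG8 mean was 0.42 (adjusted p = 0.00118, and adjusted p = 0.0948 with an estimated correlation), 0.445 on day 1 and 0.40 on day 2. Of 4 measured calmodulin-like genes, CML41 (AT3G50770), a calcium sensor of plasmodesmata, rose by 1.94 ± 0.22 and CML43 (AT5G44460) by 1.22 ± 0.29. Their list had a mean of 0.77 (adjusted p = 0.0416, and adjusted p = 0.145 with an estimated correlation). It was 0.85 on day 1 and 0.70 on day 2, and with the day as a block the adjusted p was 0.0511. The expansin list had 4 genes lower, among them EXPA8 (-0.67 ± 0.12) and EXPB1 (AT2G20750, -0.75 ± 0.16), and a mean of -0.24 that did not pass the test (adjusted p = 0.0993).

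With the hybridization day as a block, the counts in pmr4 were 980 higher and 778 lower. Day 1 alone gave 814 and 493, and day 2 alone 139 and 8.

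The responses of the 2 genotypes were set against each other across probe sets, which are not independent replicates. Their log2 changes correlated at Pearson r = 0.654 and Spearman rho = 0.448 over the 15420 probe sets, with a slope of 0.969 and the same sign for 64.4%. Over the 1580 called in wild type, a set chosen on that response alone, r was 0.893 with a slope of 0.82, and 92.5% had the same sign in pmr4. Over the 2446 called in either genotype the slope was 0.959, and 89.3% had the same sign. CHI, AT3G18250, AT5G18470 and AT2G18690 were among the 584 probe sets called higher in both genotypes, where 53.1 would be shared by independent lists of the same lengths. For 219 probe sets called lower in both the independent value was 33.7. AT5G05250 (0.76 ± 0.23 in wild type, -0.91 ± 0.23 in pmr4) and EXPA9 (0.67 ± 0.16 and -0.52 ± 0.16) were among 3 probe sets called higher in wild type and lower in pmr4. Another 1 was called in the reverse directions. The difference between the responses did not pass its own test for either gene (adjusted p = 0.0865 each). The correlation was 0.643 on day 1 and 0.466 on day 2.

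**Figure D2:**
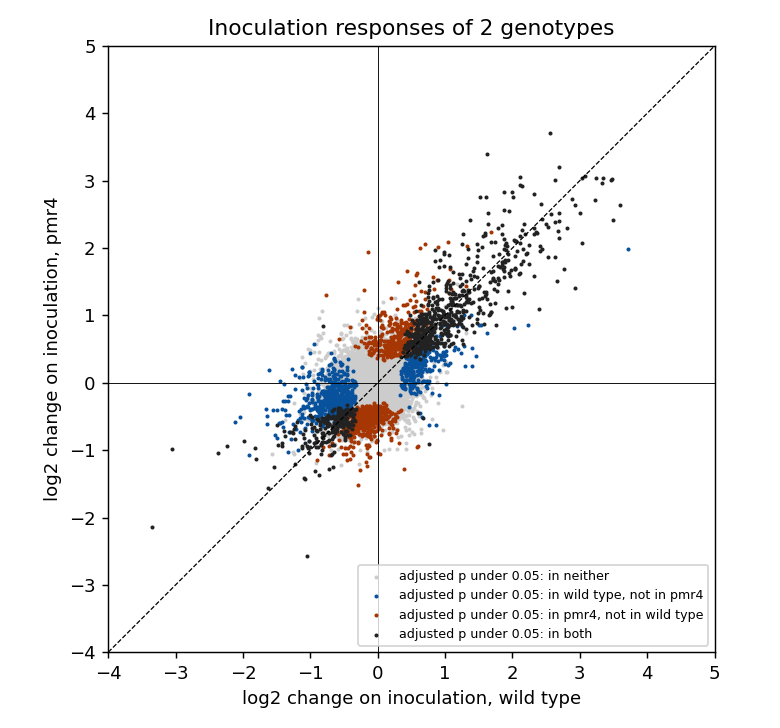
Log2 change after inoculation in pmr4 (vertical axis) against wild type (horizontal axis) for the 15420 probe sets, coloured by whether each was called in wild type, in pmr4 or in both. Most points called in both genotypes lie near the diagonal, and r over all probe sets is 0.654.

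To see what the mutation changed before infection, uninoculated pmr4 was compared with uninoculated wild type. AT1G13470 was higher by 1.73 ± 0.26 (adjusted p = 0.00464), with signals of 133 ± 31.5 in wild type and 491 ± 170 in pmr4 (SD, n = 4 each). CHI was higher by 1.61 ± 0.22 (adjusted p = 0.00261), with signals of 266 ± 78.4 and 849 ± 243 (SD, n = 4 each). AT4G00700 (1.1025 ± 0.16), AT5G39670 (1.04 ± 0.16) and the glycosyltransferase UGT87A2 (AT2G30140, 0.76 ± 0.12) were higher as well. CML41 was lower at -1.70 ± 0.22 (adjusted p = 0.00184), with signals of 449 ± 135 and 126 ± 31.6 (SD, n = 4 each). AT2G05540 (-1.17 ± 0.20), CCS (AT1G12520, -0.98 ± 0.13), the copper chaperone of superoxide dismutase, AT1G13650 (-0.95 ± 0.15) and COR47 (-0.81 ± 0.11) were lower. These 10 calls held in all 16 fits that left out 1 array and without the replicate 4 arrays, and none held on either day alone. That of AT2G05540 was lost in a fit to only the groups compared (adjusted p = 0.0576).

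Further genes of this contrast were called over all arrays but not in every fit that left out 1 array. AT2G23680 (1.46 ± 0.27) lost its call without pmr4 replicate 1 (adjusted p = 0.0655) or 2 (0.0507), and AT5G05250 (1.30 ± 0.23) without wild-type replicate 2 (0.0655) or pmr4 replicate 4 (0.0518). QQS (AT3G30720, -1.32 ± 0.24), a regulator of starch and protein content, lost its call without wild-type replicate 2 (0.0739) or pmr4 replicate 1 (0.0572). AT1G47400 (1.30 ± 0.25), AT1G65690 (1.104 ± 0.21), AT5G18470 (0.75 ± 0.15) and AT5G64180 (-0.66 ± 0.13) lost theirs in 5, 6, 6 and 7 of the 16 such fits. For AT5G52760 (1.1996 ± 0.25, adjusted p = 0.0411) and EXLA1 (-1.06 ± 0.22, adjusted p = 0.0415) the number was 9 and 11, and with the replicate block the adjusted p was 0.0691 and 0.0524. CYP71B23 (0.75 ± 0.15) lost its call in 10.

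The defence- and salicylate-associated list was higher in uninoculated pmr4, with 8 of 33 genes called higher and none lower over all probe sets, and positive differences for 27. Adjusted over the list alone, 13 were higher and 2 lower. Its mean was 0.41 (adjusted p = 5.5e-10, and 0.0258 with an estimated correlation), and 0.41 on each day. The cold and dehydration list was lower, with COR47 the only member called and a mean of -0.28 (adjusted p = 0.00151, and adjusted p = 0.152 with an estimated correlation). The mean of these genes was -0.47 on day 1 and -0.10 on day 2. Plastid-encoded photosynthesis genes had a mean of -0.17 (adjusted p = 0.000208, and adjusted p = 0.281 with an estimated correlation), -0.13 on day 1 and -0.22 on day 2, with no gene called. The nuclear list had a mean of -0.08 (adjusted p = 0.0993), the ATG8 list -0.09 (adjusted p = 0.266) and the wider folding list 0.09 (adjusted p = 0.214), none with a gene called. The calmodulin-like list had a mean of -0.52 with CML41 called (adjusted p = 0.0301, and adjusted p = 0.128 with an estimated correlation), -0.53 on day 1 and -0.52 on day 2. The expansin list had a mean of -0.13 with EXLA1 called (adjusted p = 0.108). Neither the fixed WRKY list (mean 0.32, adjusted p = 0.445) nor the fixed folding list (0.23, adjusted p = 0.0747) nor the fixed photosynthesis list (-0.10, adjusted p = 0.504) passed, and none had a gene called.

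Over all 15420 probe sets, 54 were higher and 21 lower in uninoculated pmr4 (limma, adjusted p under 0.05), 26 and 11 of them by at least 2-fold, with 21 and 9 named. Leaving out each array in turn gave 27 to 75 higher and 10 to 30 lower, with 27 and 10 without wild-type replicate 2. With the replicate block 64 were higher and 32 lower, and with the day as a block 57 and 26. Day 1 alone gave 6 higher and 3 lower, and day 2 alone 0 and 0 in limma, with 926 at an unadjusted p under 0.05. Of the 54 higher probe sets 49 were also higher in the wild-type response, where independent lists of these lengths would share 3.05, and of the 21 lower 15 were also lower, against 0.967. Both contrasts use the uninoculated wild-type arrays, so the same counts were taken with these arrays split between them, 2 to each contrast. This gave 1 to 34 probe sets higher in both over the 6 splits (mean 18.0) and 1 to 8 lower in both (mean 4.17). Across probe sets the pmr4 difference and the wild-type response correlated at r = 0.637, against 0.4999 in simulations with no effect and 0.398 to 0.470 with the arrays split, and their covariance was 0.0672 against a simulated 0.0220, a difference of 0.0452.

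**Figure D3:**
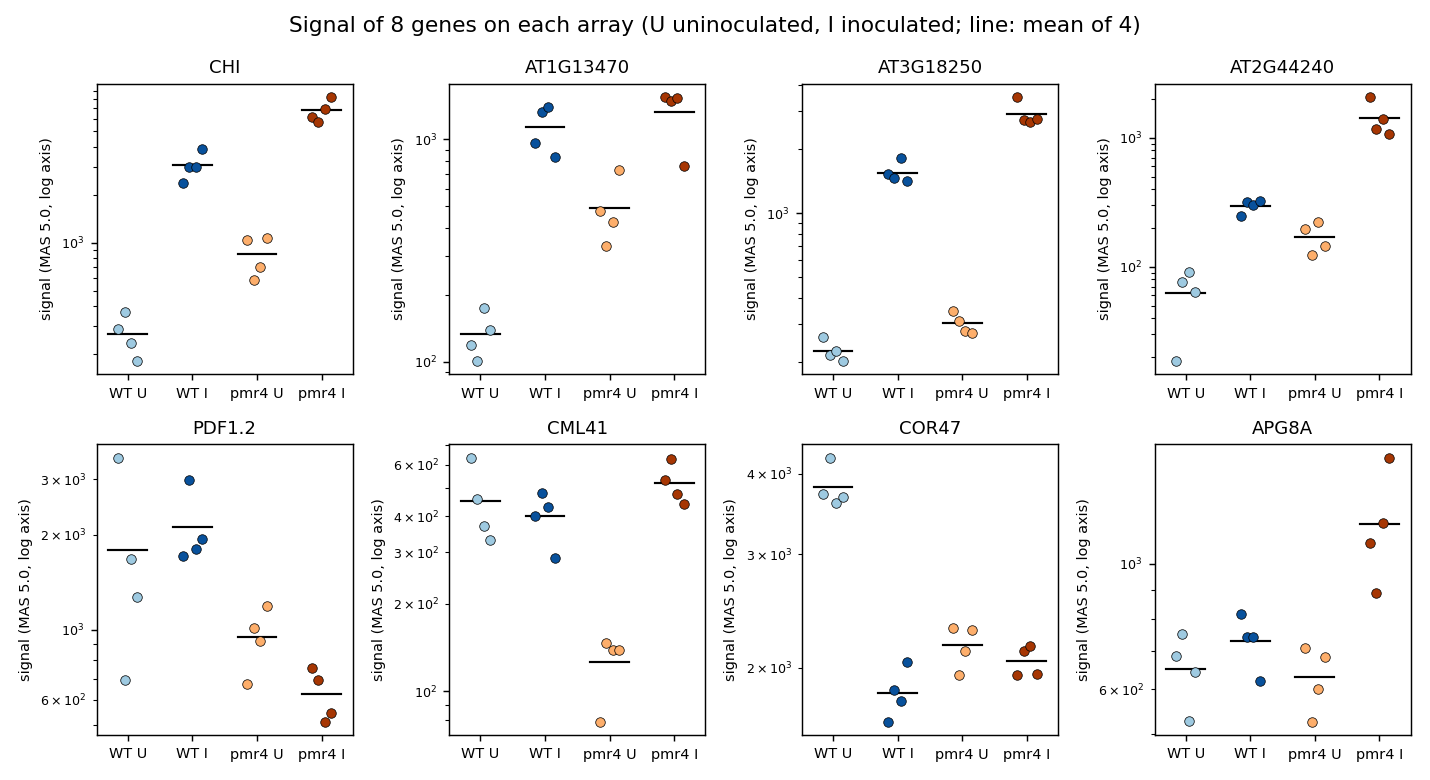
Signals of 8 genes on each of the 16 arrays, by group, on a log axis, with the group mean as a bar. CHI and AT1G13470 lie higher in uninoculated pmr4 than in uninoculated wild type, and CML41 and COR47 lower.

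The contrast of inoculated pmr4 with inoculated wild type asked whether the infected genotypes differed. AT2G44240 was higher in pmr4 by 2.17 ± 0.29 (adjusted p = 0.00231), with signals of 298 ± 35.5 in wild type and 1430.4 ± 453 in pmr4 (SD, n = 4 each). AT3G13610 was higher by 2.06 ± 0.33 (adjusted p = 0.0103), AT5G39520 by 1.90 ± 0.24 (adjusted p = 0.00131), AT1G13340 by 1.46 ± 0.17 (adjusted p = 0.000613), AT3G60420 by 1.18 ± 0.19 and AT3G18250 by 0.91 ± 0.13. AT1G31690 was lower at -0.62 ± 0.10 (adjusted p = 0.0125), and the other probe set of this gene stood at -0.53. Each of these calls held in all 16 fits that left out 1 array, and none held on either day alone. Without the 4 replicate 4 arrays the calls of AT1G13340 and AT1G31690 held, while AT2G44240, AT5G39520, AT3G60420 and AT3G18250 stood at an adjusted p of 0.0515 each and AT3G13610 at 0.114. AT3G13610 also lost its call with a pseudocount of 1 (0.0786), and AT1G31690 in a fit to only the groups compared (0.102). PDF1.2 (AT5G44420), a defensin of the jasmonate and ethylene pathways, had signals of 2111 ± 593 in wild type and 628 ± 117 in pmr4 (SD, n = 4 each), a log2 difference of -1.71 ± 0.35 with adjusted p = 0.0406. Its call was lost in 13 of the 16 such fits, with adjusted p up to 0.134, and with the replicate block (0.0692).

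AT1G57630 (1.76 ± 0.32), SBT3.3 (1.37 ± 0.28), AT3G28510 (1.33 ± 0.27) and AT1G26390 (1.32 ± 0.26) were higher in inoculated pmr4 over all arrays and lost their calls in 6, 11, 13 and 7 of the fits that left out 1 array. The lower genes AT5G15060 (-1.01 ± 0.21), AT4G15680 (-0.93 ± 0.18), AT1G13650 (-0.80 ± 0.15) and AT5G59130 (-0.68 ± 0.13) lost theirs in 12, 9, 6 and 6. With the replicate block AT5G15060 lost its call as well (adjusted p = 0.0595). CHI differed by 1.15 ± 0.22 (adjusted p = 0.0311, and 0.0579 with the replicate block), a call lost in 7.

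The defence- and salicylate-associated list was higher in inoculated pmr4, with 6 of 33 genes called higher and none lower. It had a mean of 0.45 (adjusted p = 3.2e-11, and 0.0186 with an estimated correlation), 0.42 on day 1 and 0.48 on day 2. All 9 ATG8 genes had positive differences, from 0.12 for ATG8C to 0.80 for ATG8H, although none was called over all probe sets. The mean over the list was 0.44 (adjusted p = 6.5e-07, and 0.0138 with an estimated correlation), 0.34 on day 1 and 0.53 on day 2. The mean ATG8 log2 signal was 9.73 to 9.94 on the inoculated pmr4 arrays and 9.27 to 9.54 on the other 12. The nuclear photosynthesis list was lower with no gene called (mean -0.12, adjusted p = 0.00639, and adjusted p = 0.336 with an estimated correlation). Its mean was -0.22 on day 1, -0.03 on day 2 and -0.16 without the 4 replicate 4 arrays. The plastid list had a mean of -0.07 (adjusted p = 0.108), the cold and dehydration list 0.13 (adjusted p = 0.178) and the calmodulin-like list 0.10 (adjusted p = 0.751). For expansins the mean was 0.01 and the test pointed down (adjusted p = 0.580). The wider folding list had a mean of 0.14 with no gene called (adjusted p = 0.0465, and adjusted p = 0.162 with an estimated correlation), 0.095 on day 1 and 0.18 on day 2. Its call was lost with the replicate block (0.0749) and with the day as a block (0.0519). The fixed WRKY (mean 0.21, adjusted p = 0.606), folding (0.14, adjusted p = 0.369) and photosynthesis lists (-0.07, adjusted p = 0.740) did not pass and had no gene called. Without inoculated pmr4 replicate 4 the photosynthesis list was called lower, at -0.295.

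Over all 15420 probe sets, 44 were higher and 12 lower in inoculated pmr4 (limma, adjusted p under 0.05), 26 and 5 of them by at least 2-fold, with 22 and 6 named. With each array left out in turn the counts ran from 14 to 49 higher and from 4 to 16 lower, with 14 higher without inoculated pmr4 replicate 3. Dividing each array by its median signal gave 41 and 19, so that the share of higher calls was 68.3% in place of 78.6%. With the day as a block there were 57 higher and 15 lower. Day 1 alone gave 0 and 0, with 1697 at an unadjusted p under 0.05 in limma, day 2 alone 0 and 0, with 1189, and the 12 arrays without replicate 4 gave 7 and 3. The genotype differences before and after inoculation correlated at r = 0.124 and rho = 0.0345 across probe sets, with the same sign for 49.9%. Among called probe sets 8 were higher and 2 lower in both, where independent lists would share 0.154 and 0.0163.

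**Figure D4:**
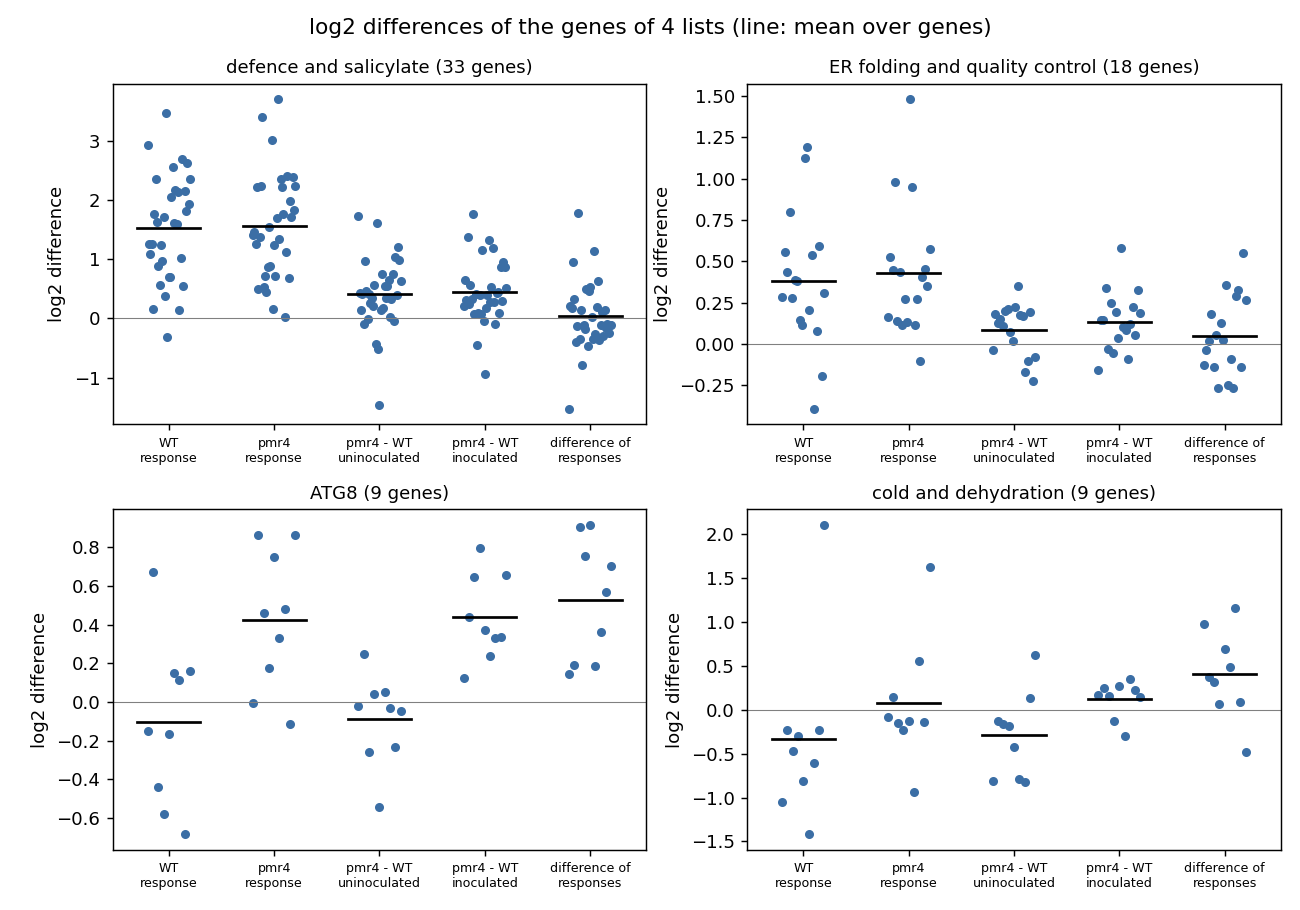
Log2 changes of the measured members of 4 gene lists in each comparison, each point a gene and each bar the list mean. The ATG8 members lie above 0 for inoculated pmr4 against inoculated wild type, with a mean of 0.44.

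The difference between the responses (pmr4 response minus wild-type response) asked whether inoculation acted differently in the mutant. It also sets fluidics modules 1 and 4 against modules 2 and 3, so a module effect cannot be told apart from it. CML41 rose by 1.94 ± 0.22 in pmr4 and stood at -0.14 ± 0.22 in wild type, a difference of 2.08 ± 0.30 (adjusted p = 0.0484). COR47 stood at -0.08 ± 0.11 in pmr4 and fell by 1.05 ± 0.11 in wild type, a difference of 0.97 ± 0.15 with the same adjusted p. For both genes the uninoculated levels differed between genotypes. COR47 signals were 3810 ± 288 in uninoculated wild type and 2168 ± 169 in uninoculated pmr4, against 1828 ± 163 and 2048 ± 113 after inoculation (SD, n = 4 each). These were the 2 probe sets called higher, and 0 were lower, in limma, with 1518 at an unadjusted p under 0.05 where 771 would be expected by chance. With the replicate block neither call was kept (0.0565 for CML41 and 0.0589 for COR47), and limma called 0 probe sets with 1784 at an unadjusted p under 0.05. With the day as a block 3 were higher and 1 lower, and each day alone gave 0 (1566 and 913 at an unadjusted p under 0.05). The calls of CML41 and COR47 were lost in 12 and 14 of the fits that left out 1 array.

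As lists, the ATG8 genes differed between the responses with a mean of 0.53 (adjusted p = 2.3e-06, and 0.0174 with an estimated correlation) and positive values for 9 of 9 genes. It was 0.45 on day 1 and 0.60 on day 2. The cold and dehydration genes had a mean of 0.41 (adjusted p = 0.000624, and adjusted p = 0.128 with an estimated correlation), with positive values for 8 of 9, and 0.53 on day 1 and 0.29 on day 2. The defence- and salicylate-associated list did not differ by the test, with a mean of 0.04, a median of -0.11 and adjusted p = 0.914. The calmodulin-like list had a mean of 0.63 with CML41 called (adjusted p = 0.0694). The plastid (0.10, adjusted p = 0.266), nuclear (-0.05, adjusted p = 0.570), expansin (0.14, adjusted p = 0.584) and wider folding lists (0.05, adjusted p = 0.600) did not pass. The fixed WRKY (-0.11, adjusted p = 0.876), folding (-0.09, adjusted p = 0.796) and photosynthesis lists (0.03, adjusted p = 0.876) did not either.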

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

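The tests of RNA quality, of scale or spread, of the shared hybridization run and of the response slope were chosen after the results were seen. The number of changed probe sets was compared with that of every other way to part the 8 arrays of a contrast into 4 and 4. In the wild-type response 1 of 35 partings, the real one, called as many as the 1580 observed, and the highest other count was 0. In the pmr4 response it was 1 of 35, with 1673 against a highest other count of 1. For uninoculated pmr4 against wild type it was 1 of 35, with 75 against 3, and for the inoculated genotypes 1 of 35, with 56 against 1. The real parting thus called the most probe sets in each of these 4 contrasts. Other partings mix the groups, which widens the spread within them and lowers their counts. As 1 of 35 is the lowest share possible and the hybridization run is ignored, chance was not excluded for these 4 counts. Among the 8 partings that put 1 array of each run on each side, the highest other counts were 0, 1, 0 and 0, and 8 are too few for a share under 0.05. The other partings, which put both arrays of a run together, gave at most 0, 1, 3 and 1. For the difference between the responses 2 of 100 draws of the genotype labels, the real one included, called as many as the 2 observed, and the highest other count was 2, again with the run ignored.

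The difference between the genotypes' responses passed its own test for CML41 (2.08), COR47 (0.97), the ATG8 list (mean 0.53) and the cold and dehydration list (mean 0.41). The calls of CML41 and COR47 were lost with the replicate block (adjusted p = 0.0565 and 0.0589 in limma), and that of the cold and dehydration list with an estimated correlation (adjusted p = 0.128). Only the ATG8 list was examined further.

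The first pattern was the shift of uninoculated pmr4 plants toward the inoculated state, with CHI and AT1G13470 among its members. Shared control arrays were argued against as its whole source. The correlation with the wild-type response was still at least 0.398 when the 2 contrasts used different control arrays. A fluidics module effect was not tested and stayed open. Uninoculated pmr4 and inoculated wild type were on modules 2 and 3, and every control array was on module 1 or 4. Such an effect would remain in each split. RNA quality stayed open: the largest of 6 differences in the log2 ratio of 3' to 5' signal was 0.213, for ubiquitin in the older controls (exact permutation p = 0.171, two-sided), and 4 arrays against 4 leave little power. Stray infection of the uninoculated mutant plants also stayed open, because probe sets that rose in the wild-type response were shifted by a mean share of 0.311 of that response (0.268 to 0.370 over the splits of the controls) and those that fell by 0.357 (0.321 to 0.397), which both a low level of infection and constitutive defence in the mutant could give. Fungal transcripts or counts of colonies on the uninoculated plants would separate the last 2.

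The second pattern was the distance of the inoculated replicate 4 arrays from the other inoculated arrays, and the uninoculated arrays of that replicate were the lowest of their groups on the second component too, at -11.3 and -19.2. RNA quality stayed open for both arrays. In wild type 2 of 6 control ratios lay outside the range of the 14 other arrays, in opposite directions. The newer ubiquitin stood above it at 1.32 (highest other 0.781) and the older GAPDH below it at 0.112 (lowest other 0.270). In pmr4 1 of 6 lay outside, the older ubiquitin at 2.095 (highest other 2.01). Scale or spread of the signals was argued against as the whole source, as quantile normalization lowered the root mean square log2 distance from the rest of the group from 0.473 to 0.459 in wild type and from 0.499 to 0.453 in pmr4, still above the highest of the 14 others (0.399). A shared run may account for the pattern, but this was not decided. The mean correlation of deviations of 0.189 within the run of replicate 4 largely restates that its arrays were seen to deviate together. Plants grown and run together cannot be separated here. A stronger response was not decided for these plants as a pair. The slope on the other genotype's response was -0.0554 in wild type, which shows no stronger response and lies within the range of the 14 other arrays. In pmr4 the slope was 0.07, above that range, and a stronger response stayed open. The slopes of the 14 other arrays ran from -0.117 to 0.0628.

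The third pattern was the higher level of ATG8 genes in inoculated pmr4. The inoculated pmr4 replicate 4 array alone was argued against as its source. The other inoculated pmr4 arrays had mean ATG8 log2 signals of 9.73 to 9.81, against 9.27 to 9.53 on the inoculated wild-type arrays. The difference between the responses, which also takes in the uninoculated arrays, had a mean of 0.48 without that array (camera, adjusted p = 0.0452 with an estimated correlation). Array scaling was argued against for the difference between the responses, with a mean of 0.53 after quantile normalization. A fluidics module effect was not tested and cannot be told apart from this pattern. More autophagy in the mutant after infection could give this pattern, but transcripts alone do not measure it, and an assay of ATG8 protein turnover would be the test.

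Single arrays far from the other 3 of their group were sought with Dixon's ratio, the gap to the nearest array over the range of the group, against its 95% critical value for 4 arrays. By chance about 1 in 20 groups pass this value. For genes 36 of 532 tests did where 26.6 would be expected, and for measures of whole arrays 1 of 40 where 2 would be. Inoculated pmr4 replicate 4 was the distant array for 11 genes: AT1G13470 (0.932), AT5G18470 (0.916), AT2G15830 (0.843), LHCB4.2 (0.830), SWEET11 (0.914), EXPA9 (0.837), GAMMA-VPE (0.886), Hsp70-2 (0.874), AT3G24190 (0.955), AT2G34250 (0.980) and EXPB3 (0.915). Inoculated pmr4 replicate 1 was the distant array for AT3G18250 (0.850) and CaS (0.864), and replicate 2 for BCAT4 (0.843), AT3G60540 (0.893) and AT3G13610 (0.896).

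Among the uninoculated pmr4 arrays, replicate 1 was distant for the GAPDH ratio of 3' to 5' signal (0.858), CML41 (0.904) and BGLU42 (0.934), replicate 2 for AT3G13610 (0.854), and replicate 3 for AT5G62280 (0.840) and GSTF4 (0.856). Replicate 4 was distant for GI (0.848), SBT3.5 (0.842), S1P (0.872) and the ATG8 list mean (0.844). In uninoculated wild type, replicate 1 was distant for AT2G18690 (0.871) and TAPX (0.851), replicate 2 for psbM (0.856), and replicate 4 for AT5G50335 (0.982) and AT1G31690 (0.874). In inoculated wild type, replicate 1 was distant for UGT73D1 (0.884), SWEET11 (0.880) and COR15B (0.906), and replicate 4 for NdhN (0.867), AT3G24190 (0.892), SWEET13 (0.890) and GSTU26 (0.949).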

How the results depend on the processing

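The fits of each hybridization day alone and without the 4 replicate 4 arrays were chosen after the data had been seen. Counts below are higher then lower probe sets, and list values are mean log2 changes. Where a value moved, the cause was not tested unless stated. A stricter threshold lowers the counts by construction. The setting of 1 probe set per named gene also leaves out every probe set not matched to a gene by locus. Its lower counts are therefore set beside the named calls of the main fit. Among changes of single named genes (665 gene and contrast pairs), leaving out 1 array left the result on its side of the threshold, called or not, in 10173 cases, ended a call in 429 and brought one in 38. Other settings left it there in 8511, ended a call in 436 and brought one in 115, and none reversed. For lists the leave-one-out fits left 1630 results on their side of the threshold, ended 34 calls and brought 16, and other settings left 1580, ended 43, brought 25 and reversed 1. Apart from the WRKY calls, the list calls ended by leaving out 1 array were in the second family of lists and are not named one by one. Genes below a minimum signal of 200 gave no value there, and the difference between the responses has no fit to only the groups compared. The reversed value was the fixed photosynthesis list in the pmr4 response, -0.30 on day 1 alone (adjusted p = 0.042) against 0.02 over all arrays (adjusted p from 0.042 to 0.976 over its alternatives).

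In the wild-type response the counts moved under array quality weights (1231 lower), a 2-fold minimum (319, 110), an adjusted p under 0.01 (546, 314), 1 probe set per named gene (379, 299, against 421 and 358 named calls in the main fit), day 1 (369 lower) and day 2 (150, 65). In the pmr4 response they moved under array quality weights (1174 lower), a fit to only the groups compared (398 lower), a 2-fold minimum (338, 37), an adjusted p under 0.01 (577, 255), 1 probe set per named gene (434, 337, against 462 and 380 named calls in the main fit), day 1 (493 lower) and day 2 (139, 8).

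For uninoculated pmr4 against wild type, the moved counts were 38 lower with a pseudocount of 64, 35 higher without a filter, 84 and 35 with a minimum signal of 200, 86 and 37 with an intensity trend, 205 and 112 with array quality weights, 35 higher with only the groups compared, 32 lower with the replicate block, 26 and 11 with a 2-fold minimum, 23 and 10 at an adjusted p under 0.01, 14 and 7 with 1 probe set per named gene (against 21 and 9 named calls in the main fit), 6 and 3 on day 1, and 0 and 0 on day 2 (limma, 926 at an unadjusted p under 0.05). For the inoculated genotypes they were 88 and 24 with a pseudocount of 64, 24 and 6 without a filter, 23 lower with a minimum signal of 200, 22 lower with quantile normalization, 19 lower after division by the median, 28 lower with an intensity trend, 70 and 33 with array quality weights, 5 lower with only the groups compared, 26 and 5 with a 2-fold minimum, 10 and 2 at an adjusted p under 0.01, 22 and 5 with 1 probe set per named gene (against 22 and 6 named calls in the main fit), 0 and 0 on day 1 and on day 2 (limma, 1697 and 1189 at an unadjusted p under 0.05), and 7 and 3 without the replicate 4 arrays.

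For the difference between the responses, limma called 0 with a pseudocount of 1, without a filter, with the replicate block, on either day, without the replicate 4 arrays and at an adjusted p under 0.01, with 1498, 1892, 1784, 1566, 913, 1828 and 1518 at an unadjusted p under 0.05. It called 10 and 5 with a pseudocount of 64, 9 and 5 with a minimum signal of 200, 6 and 3 with quantile normalization (66.7% higher, against 100% of the 2 calls), 1 and 0 after division by the median or with a 2-fold minimum, 15 and 6 with an intensity trend, 10 and 4 with array quality weights, and 3 and 1 with the day as a block. Over all alternatives the adjusted p ran from 0.00898 to 0.582 for CML41 and from 0.00575 to 0.838 for COR47. Without a filter, the responses correlated at r = 0.479 and rho = 0.304, and on day 2 at r = 0.466 and rho = 0.345.

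Of the fixed lists, WRKY in the pmr4 response lost its call with a pseudocount of 1 (1.1038), quantile normalization (1.06), day 2 (0.57) and the estimated correlation (1.03), and in the wild-type response with the estimated correlation (1.14). The folding list lost its calls with the estimated correlation (0.68 in wild type, 0.59 in pmr4), and was called higher in uninoculated pmr4 with quantile normalization (0.24), an intensity trend (0.23), only the groups compared (0.23) and without the replicate 4 arrays (0.21). Photosynthesis was called lower in inoculated pmr4 with array quality weights (-0.21), on day 1 (-0.27) and without the replicate 4 arrays (-0.22).

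The replicate block, which respects the pairing by run, moved the lower count in uninoculated pmr4 from 21 to 32 and the difference between the responses from 2 to 0. It also ended the calls of psbM (0.0532) and ATG8H (0.0644) in the wild-type response and of AT5G15060 in the inoculated genotypes (0.0595). It brought calls for UGT73D1 in the inoculated genotypes (0.0299), atpI (0.0483), GAMMA-VPE (0.0167) and Fes1B (0.0467) in the pmr4 response, and BGLU16 (0.0318), AT2G34250 (0.0372), EXPB1 (0.0341) and LTI30 (0.0436) in the wild-type response, each as the adjusted p of limma. Beyond these and the values given with the results it changed no other call among the 665 pairs of named gene and contrast or the lists. Over all probe sets it kept 1506, 1594, 69 and 47 of the calls in the first 4 contrasts and called 1769, 1828, 96 and 64.

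With each array left out in turn, the counts ran over 673–1028 higher and 449–915 lower in the wild-type response, 771–1041 and 488–946 in the pmr4 response, 27–75 and 10–30 for uninoculated pmr4, 14–49 and 4–16 for the inoculated genotypes, and 0–3 and 0–2 for the difference between the responses. The correlation of the responses ran over 0.618–0.666 (r) and 0.392–0.470 (rho), and the slope over 0.800–0.835. List means ran over 1.07–1.32, 0.80–1.21, 0.14–0.56, 0.10–0.29 and -0.34 to 0.07 for WRKY in the 5 contrasts in the same order, over 0.63–0.72, 0.47–0.65, 0.20–0.25, 0.02–0.20 and -0.21 to -0.03 for folding, and over -0.08 to 0.04, -0.20 to 0.14, -0.12 to -0.08, -0.30 to 0.0427 and -0.19 to 0.14 for photosynthesis.

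Single arrays that moved a count by more than 1.5 times were, in the wild-type response, uninoculated wild-type replicates 1 (457 lower) and 2 (449). For uninoculated pmr4 they were wild-type replicates 1 (13 lower), 2 (27 and 10) and 4 (33 higher) and pmr4 replicates 1 (29 and 13) and 4 (29 higher). For the inoculated genotypes they were wild-type replicates 1 (24 and 4) and 4 (24 and 7) and pmr4 replicates 1 (25 higher), 2 (18 and 4), 3 (14 and 7) and 4 (22 and 7). For the difference between the responses, 11 arrays gave 0 higher (limma, 1245 to 1612 at an unadjusted p under 0.05), uninoculated wild-type replicate 4 and inoculated wild-type replicate 1 gave 1, and uninoculated wild-type replicate 3 and inoculated pmr4 replicate 4 gave 2 and 1 lower. The WRKY call in the pmr4 response was lost without uninoculated or inoculated wild-type replicate 1 or inoculated wild-type replicate 4 (1.03 each), uninoculated pmr4 replicate 2 (1.01) or 3 (0.80), or inoculated pmr4 replicate 2 (1.02) or 3 (0.99). Without uninoculated pmr4 replicate 3 WRKY was called in uninoculated pmr4 (0.56), without uninoculated wild-type replicate 2 or inoculated pmr4 replicate 4 folding was called there (0.25 and 0.23), and without inoculated pmr4 replicate 4 photosynthesis was called in inoculated pmr4 (-0.30). Signal over background limits the dim genes: 15420 of 22746 probe sets reached a signal of 100 on 4 arrays, and changes below it are shrunk by the pseudocount.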

Other observations

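Enzyme and transporter families without a shift as a list still held genes that responded to inoculation. Among 23 UDP-glycosyltransferases, UGT73D1 (AT3G53150) rose in pmr4 from signals of 7.1 to 52.8 to signals of 132 to 264, UGT87A2 rose by 1.79 ± 0.12 and 1.46 ± 0.12, and UGT76E11 (AT3G46670) fell by 0.69 ± 0.13 in pmr4. Of 10 SWEET sugar transporters, SWEET2 (AT3G14770) fell by 0.49 ± 0.12 in wild type and 0.61 ± 0.12 in pmr4, SWEET13 fell by 1.06 ± 0.16 in pmr4, and SWEET11 (AT3G48740) rose by 0.46 ± 0.13 in wild type (adjusted p = 0.0333). Leaving out 1 array ended the wild-type calls of SWEET2 in 2 of 16 fits and of SWEET11 in 4. The glutathione transferase GSTF4 (AT1G02950) fell by 0.79 ± 0.16 in pmr4, and CYP71B6 (AT2G24180) rose by 0.69 ± 0.12 in wild type. Of the trichome birefringence-like genes, which acetylate wall polymers, TBL36 (AT3G54260) fell by 0.95 ± 0.19 in wild type and TBL41 (AT3G14850) by 1.06 ± 0.26 in pmr4. The subtilase SBT3.5 (AT1G32940) rose by 1.12 ± 0.14 in wild type and 1.33 ± 0.14 in pmr4, the chaperone Hsp70-2 (AT5G02490) by 1.14 ± 0.14 and 1.00 ± 0.14, and the beta-glucosidase BGLU25 (AT3G03640) by 0.87 ± 0.17 in pmr4. The thionin THI2.2 (AT5G36910) fell by 1.05 ± 0.20 and 0.93 ± 0.20. Each of these genes passed the limma test in the contrast given.

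As lists, none of these families passed camera in any of the 5 contrasts. The lowest adjusted p was 0.178 for UDP-glycosyltransferases, 0.150 for SWEET transporters, 0.107 for glutathione transferases, 0.0993 for the CYP71B family, 0.150 for trichome birefringence-like genes, 0.171 for subtilases and vacuolar processing enzymes, 0.233 for heat shock chaperones, 0.752 for beta-glucosidases, 0.582 for jasmonate and ethylene genes and 0.904 for AGAMOUS-like and pollen or floral regulators. In the pmr4 response the subtilase list had a mean of 0.38 and a median of -0.06, and for the inoculated genotypes the jasmonate and ethylene list had a mean of -0.25 and a median of 0.08. SBT3.3 at 2.21 and PDF1.2 at -1.71 lay far from the medians of their lists.

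Of the fixed lists too small to test, BCAT4 (AT3G19710) of methionine-derived glucosinolate synthesis fell by 0.49 ± 0.11 in the pmr4 response (adjusted p = 0.00917). The pattern receptor EFR (AT5G20480, 0.68 ± 0.22 in pmr4, adjusted p = 0.0561), the clock gene GI (AT1G22770, -0.24 ± 0.20 in wild type), the stress-responsive zinc finger gene STZ (AT1G27730, 0.89 ± 0.46 in wild type) and the guard cell regulator FMA (AT3G24140, -0.10 ± 0.20 in wild type) were called in no contrast. PDF1.2b (AT2G26020) stood at -1.31 ± 0.47 for inoculated pmr4 against wild type (adjusted p = 0.281), in the direction of PDF1.2.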
